A study of Mus musculus with 3 samples.

How the data were processed

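RNA was sequenced from whole sciatic nerves of 3 mice or nerve preparations that carry the Nmnat2 V98M and R232Q alleles on a SARM1 knockout background, at 2 months of age per the labels. All 3 samples belong to 1 group, taken with its replicate numbers from the sample titles. The labels do not say whether a sample is 1 nerve, 1 animal or a pool, nor the sex of the animals, so biological and technical spread cannot be separated. The study's design text names wild-type nerves as the other arm; wild-type nerves are not analysed here, and no comparison between genotypes was made.

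The unit of the deposited table is a count per Ensembl gene, taken from its name; all values are whole numbers and no normalization is stated. RNA was extracted with Trizol and chloroform, cleaned on a column and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The submitters' processing notes list bcl2fastq, STAR 2.5.1a, Subread, featureCounts 1.4.6-p5, Salmon 0.8.2 and the build mm10, with no role or order. The annotation release, strand setting, treatment of multi-mapped reads and read length are not given in the sources used here. The deposited counts from 1 to 9 were even in 69.1%, 67.8% and 69.9% of genes in replicates 1, 2 and 3, against 50.2%, 50.2% and 49.9% of counts of 100 or more. Counting both mates of a read pair would give such an excess, but this was not tested. Intervals from counts cover counting error only, and would be too narrow if both mates were counted. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart.

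The table had 40757 lines for 40481 genes. The 276 repeated lines held the same counts as the first line of their gene and were dropped. The table held 0 further sample columns. Gene positions, exon lengths and transcript sequences came from GENCODE release M21 (GRCm38, the assembly also called mm10), which held 40254 of the genes (99.4%). Of the 369 entries in the gene lists, 3 were not in the table: Trdc, and the synonyms Bmal1 and Cyr61 of genes listed under Arntl and Ccn1.

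Counts were scaled to CPM (counts divided by the scaled library total, times 1e6) with TMM factors of edgeR 4.0.16 in R 4.3.3, which lay between 0.993 and 1.01. A gene was called detected at a CPM of at least 1 in each of the 3 libraries. Log2 CPM used a prior count of 2. Genes kept by filterByExpr (17387) were fitted with an intercept-only design (estimateDisp, glmQLFit, robust=FALSE). A gene's quasi-likelihood dispersion was divided by its prior value and tested with an F test on 2 residual and 6.9 prior degrees of freedom, with Benjamini-Hochberg adjustment at 0.05. This asks whether a gene varied more between the 3 libraries than genes of like abundance. With 1 group, no test across genes between groups was possible. The 29 gene lists were fixed before the data were examined. Each was described by its members detected, the sum of its members' CPM and its shift, the mean over tested members of log2 CPM minus the gene's own mean. The SD of that shift over the 3 libraries was placed among 10000 random lists of the same size matched on expression (20 bins), for lists with at least 3 tested members. Genes are not independent replicates, so percentiles are descriptions without a p-value. Levels of lists were compared within libraries as log2 ratios of median CPM per kb of exon (pseudocount 0.01), with an exact two-sided sign-flip test whose smallest p with 3 libraries is 0.25. Alternatives were DESeq2 1.42.0 size factors and dispersion outliers, no scaling factors, no filter, other detection limits, edgeR's robust and goodness-of-fit options, mitochondrial genes left out, and each replicate left out.

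The rule for named genes, set before the data were examined, took Sarm1 and Nmnat2, the 10 most abundant genes, the 3 most abundant detected members of each list (1 for lists whose median member was under 1 CPM), the 10 genes with the smallest p among those that varied, and up to 4 list members that varied. Other genes named are said to have been chosen after their values were seen.

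The variation test was tested on simulated data for this group with 17597 genes tested and 200 changed in a random replicate. It called 25.4% of genes changed 2-fold, 80.6% of those changed 4-fold and 90.9% of those changed 8-fold, with 12 unchanged genes called. The list statistic put 7 of 100 unshifted random lists and 100 of 100 lists with a shift of 0.5 log2 units in 1 replicate at or above the 95th percentile. Total counts were 30792010, 30510650 and 28618554 in replicates 1, 2 and 3. A count of 0 allows a level of up to 0.0974, 0.0983 and 0.105 CPM in them, taken as 3 counts of the total. These limits would be too low if both mates of a read pair were counted.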

Results

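Bulk RNA-seq profiled sciatic nerve, the mixed nerve of the hind limb, from 2-month-old mice with the Nmnat2 V98M and R232Q alleles and a Sarm1 knockout. Nmnat2 encodes an axonal enzyme of NAD synthesis, and Sarm1 encodes the NAD-cleaving enzyme of programmed axon degeneration. There were 3 libraries of 30792010, 30510650 and 28618554 counts. At least 1 count was found for 24162, 24418 and 24053 genes, and 14822 genes, 13049 of them protein-coding, reached 1 CPM in all 3. The libraries were not copies of each other: a chi-square statistic over genes was 11.96, 10.7 and 12.6 times its degrees of freedom for the 3 pairs. The between-replicate coefficient of variation was 10.8%, and the median SD of log2 CPM was 0.13 over 17387 genes (n = 3). Whether the libraries are separate animals is not labelled, so p-values measure only the spread between these samples. The series names wild-type nerves as its other arm, and these are not analysed here, so levels below are those of the mutant knockout nerves alone.

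Sarm1 transcripts were few, below the detection limit of 1 CPM in each library, and Nmnat2 transcripts were present at a moderate level. Sarm1 (ENSMUSG00000050132, GRCm38 chromosome 11, 78472330 to 78497754, minus strand) had 16, 19 and 7 counts, a level of 0.461 ± 0.193 CPM (SD, n = 3). Nmnat2 (ENSMUSG00000042751, chromosome 1, 152954993 to 153119261, plus strand) had 902, 795 and 782 counts, or 27.6 ± 1.68 CPM. The table has 1 count per gene and no exon or allele counts. It therefore shows neither whether the Sarm1 counts fall in the disrupted part of the gene nor how much Nmnat2 RNA comes from each allele. Of the 17 genes in the NAD metabolism list, 14 were detected and none varied between replicates. The most abundant were Slc25a51, a mitochondrial NAD transporter (116 ± 2.62 CPM), the NAD kinase Nadk (110 ± 4.14 CPM) and Parp1 (54.8 ± 4.60 CPM).

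The 18 myelin genes were all detected and together made up 8.44% of all counts (84442 ± 5196 CPM). Mbp (17690 ± 883 CPM), Pmp22 (12440 ± 879 CPM) and Prx (6011 ± 43.6 CPM) were among the 10 most abundant genes of the table. So were Gm26917 (23340 ± 1612 CPM) and Malat1 (21990 ± 205 CPM), both annotated as long non-coding RNAs. Whether the reads of Gm26917 come from such an RNA or from repeated sequence was not tested. The small RNAs Rn7sk (12740 ± 244 CPM) and Rpph1 (5786 ± 559 CPM) were also among the 10, as were the protein-coding Ahnak (9668 ± 498 CPM) and Sparc (5607 ± 410 CPM). The 18 genes of cholesterol synthesis, which supplies myelin lipid, were all detected at a sum of 4604 ± 298 CPM, with Hmgcs1 at 1041 ± 79.7 CPM and Srebf2 at 499 ± 13.6 CPM.

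All 10 genes of non-myelinating Schwann cells were detected, at a sum of 1645 ± 59.0 CPM, with Scn7a (506 ± 30.8 CPM), Gas7 (438 ± 5.69 CPM) and Cdh19 (224 ± 11.3 CPM) highest. Of the 14 genes that mark injured or repair Schwann cells, 6 were detected and the median member was at 0.903 CPM. The most abundant was the adhesion gene Cdh1 (317 ± 27.0 CPM), which uninjured Schwann cells also express. The other 5 detected members, named after their values were seen, were Jun (58.2 ± 9.77 CPM), Lif (16.5 ± 1.51 CPM), Atf3 (13.1 ± 4.41 CPM), Runx2 (5.12 ± 0.716 CPM) and Shh (1.62 ± 0.398 CPM). The median myelin gene exceeded the median non-myelinating Schwann gene by 4.30 ± 0.17 log2 units per kb of exon and the median injury gene by 9.41 ± 0.17. Each difference had the same direction in 3 of 3 libraries, and the exact two-sided sign-flip p was 0.25, the smallest that 3 libraries can give. The first difference depends on the measure, since it was 3.06 without length scaling and 6.09 with means over members. The second difference depends on undetected genes, since it was 5.74 with detected members only.

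**Figure D1:**
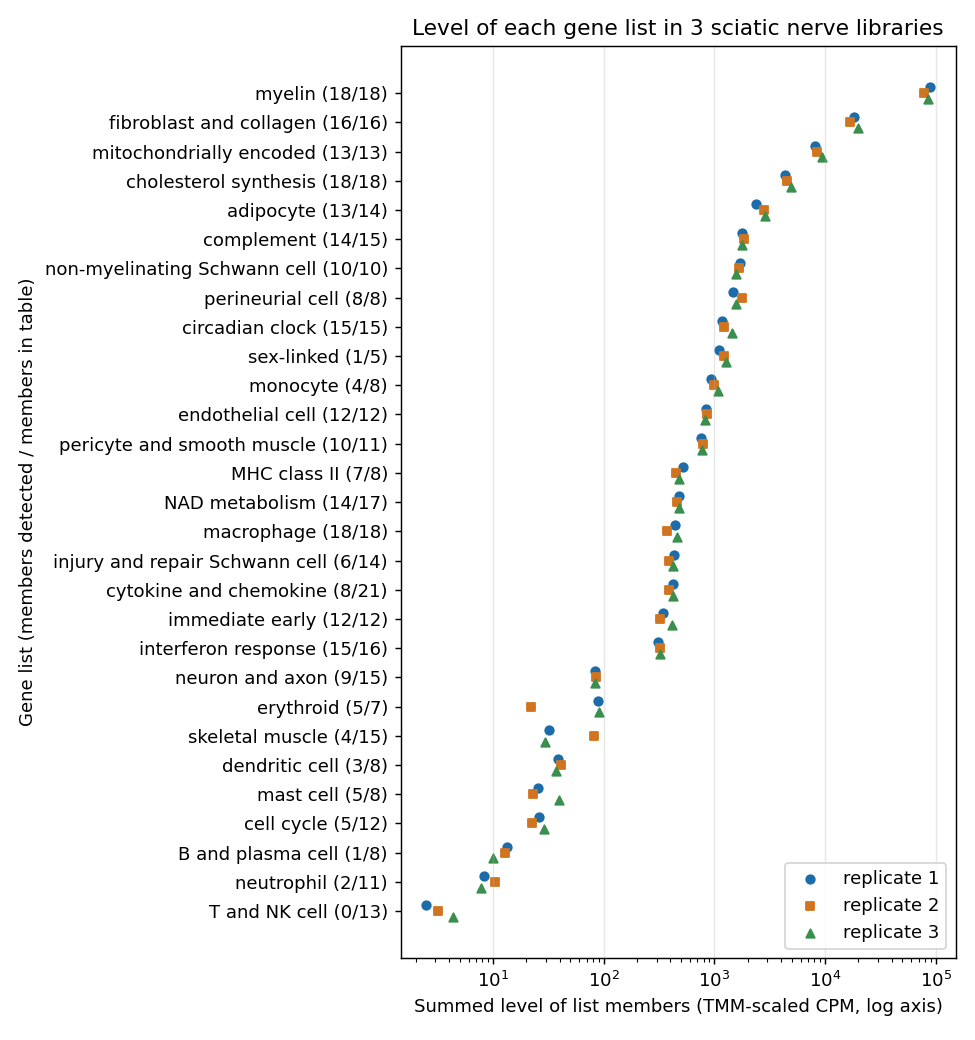
Summed TMM-scaled CPM of each of the 29 gene lists (log axis) in the 3 replicates, with the number of members detected and in the table beside each name. Myelin lies highest at 84442 CPM on average and T and NK cell genes lowest at 3.33 CPM, and replicate 2 stands apart for the erythroid and skeletal muscle lists.

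Among immune transcripts, those of macrophages were found throughout, and most genes of the lymphocyte and neutrophil lists were not detected. All 18 macrophage genes were detected, at a sum of 423 ± 44.1 CPM, led by the CSF1 receptor gene Csf1r (81.2 ± 4.64 CPM), the mannose receptor gene Mrc1 (63.1 ± 5.72 CPM) and the scavenger receptor gene Cd163 (51.3 ± 14.7 CPM). Of 8 MHC class II genes 7 were detected (483 ± 31.0 CPM), led by Cd74 (144 ± 12.3 CPM), H2-DMb1 (84.3 ± 6.82 CPM) and H2-DMa (77.8 ± 5.86 CPM). None of the 13 T and NK cell genes in the table was detected at 1 CPM in all libraries (sum 3.33 ± 0.961 CPM), and Cd3e was at 0.772 ± 0.350 CPM. Of 11 neutrophil genes 2 were detected (8.83 ± 1.32 CPM), led by Mmp9 (5.67 ± 1.55 CPM), and Ly6g and Cxcr2, named after their values were seen like the other genes at 0 below, had 0 counts in each library. Of 8 B and plasma cell genes only Ighm was detected (9.78 ± 1.85 CPM).

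Mast cell genes were detected for 5 of 8 members (29.2 ± 8.89 CPM), led by Kit (7.86 ± 3.38 CPM), Tpsb2 (7.01 ± 3.32 CPM) and Mcpt4 (6.43 ± 0.944 CPM). Of 8 dendritic cell genes 3 were detected, with Zbtb46, which endothelial cells also express, highest at 26.5 ± 2.64 CPM (sum 38.7 ± 1.91 CPM). Of 8 monocyte genes 4 were detected (1000.03 ± 81.2 CPM). That sum came mainly from Fn1 (910 ± 69.0 CPM) and Vcan (77.2 ± 11.4 CPM), matrix genes that other nerve cells also express, while Ccr2 was at 7.87 ± 0.267 CPM and Chil3 and Clec4e had 0 counts. The median macrophage gene exceeded the median gene of the T and NK list by 6.38 ± 0.53 log2 units per kb, of neutrophils by 5.73 ± 0.41, of B and plasma cells by 4.96 ± 0.45 and of monocytes by 3.49 ± 0.29. With detected members only, the ratios over neutrophil, B and plasma cell and monocyte genes were 2.83, 0.62 and 1.28, so their size depends on undetected genes. All 4 ratios of medians over all members were above 0 in 3 of 3 libraries (exact two-sided sign-flip p = 0.25 each, the smallest possible). With means in place of medians the last ratio turned to -0.01, since Fn1 and Vcan then weigh most.

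Cytokine and chemokine genes were detected for 8 of 21 members (413 ± 20.9 CPM), and the highest was Cxcl12 (166 ± 13.1 CPM). The inflammatory cytokine genes Il1b, Il6 and Tnf, named after their values were seen, had 4, 4 and 1 counts, 0, 2 and 0 counts, and 12, 8 and 6 counts. Of 16 interferon response genes 15 were detected (317 ± 5.11 CPM), with Xaf1 (143 ± 8.25 CPM) well above Ifit2 (33.8 ± 1.77 CPM). Complement genes were detected for 14 of 15 members (1812 ± 35.5 CPM), led by C4b (441 ± 24.5 CPM), Cfd (437 ± 38.5 CPM) and C3 (382 ± 47.9 CPM). Cfd is also in the adipocyte list.

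The stroma and vessels of the nerve were strongly represented. All 16 fibroblast and collagen genes were detected (18240 ± 1609 CPM), led by Col1a1 (5429 ± 498 CPM), Col1a2 (4205 ± 352 CPM) and Col3a1 (3617 ± 588 CPM). All 8 perineurial genes were also detected (1605 ± 163 CPM), led by Itgb4 (1130 ± 130.4 CPM), Slc2a1 (196 ± 34.2 CPM) and Tenm2 (123 ± 15.7 CPM). Itgb4 made up most of that sum, and whether perineurial cells were its source was not tested. All 12 endothelial genes (839 ± 20.9 CPM, led by Vwf at 299 ± 8.05, Cldn5 at 86.2 ± 6.02 and Cdh5 at 79.1 ± 9.78 CPM) and 10 of 11 pericyte and smooth muscle genes (769 ± 16.0 CPM, led by Pdgfrb at 232.4 ± 14.0, Notch3 at 127 ± 8.93 and Tagln at 127 ± 2.60 CPM) were detected. Adipocyte genes were detected for 13 of 14 members (2695 ± 264 CPM), led by the lipid synthesis genes Fasn (1086 ± 118 CPM) and Scd1 (703 ± 50.6 CPM), which Schwann cells also express.

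Axonal and neuronal genes were sparse, with 9 of 15 detected (83.7 ± 0.870 CPM), led by Uchl1 (33.3 ± 1.51 CPM), Nefh (12.9 ± 0.492 CPM) and Stmn2 (7.37 ± 1.10 CPM). Cell cycle genes were detected for 5 of 12 members (25.7 ± 2.99 CPM), led by Mki67 (9.94 ± 1.64 CPM), Top2a (4.15 ± 0.430 CPM) and Plk1 (2.52 ± 0.148 CPM). All 15 circadian clock genes in the table were detected (1277 ± 146 CPM; Per1 302.5 ± 96.3, Nr1d1 156 ± 17.8 and Per3 149 ± 16.1 CPM), as were all 12 immediate early genes (359 ± 47.8 CPM; Nr4a1 146 ± 24.3, Ccn1 44.6 ± 7.70 and Zfp36 43.5 ± 12.2 CPM). The 13 mitochondrially encoded genes summed to 8626 ± 604 CPM, led by mt-Co1 (2951 ± 172 CPM), mt-Cytb (1843 ± 86.5 CPM) and mt-Nd5 (1206 ± 88.4 CPM). Of the 5 sex-linked genes, Xist, which is expressed from the inactive X chromosome, was at 1085, 1208 and 1259 CPM, and the Y-linked Ddx3y, named after its values were seen, had 162, 0 and 0 counts in replicates 1, 2 and 3.

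With a single labelled genotype, the difference left to test was that between nerves. Of 17387 genes, 39 varied between the 3 libraries more than genes of like abundance (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). An unadjusted p under 0.05 in that test was found for 817 genes. That is less than a share of 0.05 of the genes tested. The prior value and its degrees of freedom were estimated from these same genes. A share near 0.05 therefore follows from the fit, and shows neither an excess over chance nor its absence. With the robust option of the same fit 0 genes passed (smallest adjusted p = 0.997), so the calls rest on that choice. Mt2, a metallothionein, had 133, 50.8 and 309 CPM (adjusted p = 0.00212, n = 3), and Mt1 had 108, 61.7 and 194 CPM (0.00789). The glucocorticoid receptor co-chaperone gene Fkbp5 had 63.9, 36.7 and 155 CPM (0.00493), the transcription factor gene Zbtb16 had 135, 77.9 and 270 CPM (0.00789) and Hif3a had 30.6, 18.1 and 75.2 CPM (0.00789). Of the 39 genes, 23 were highest in replicate 3 and 24 were lowest in replicate 2, and 19 had the order replicate 3, 1, 2. Cadps2, which encodes a protein of vesicle exocytosis, differed by 5.70-fold and was highest in replicate 1, with 148, 25.99 and 48.6 CPM (0.00212). Gm22701 (12.3, 13.7 and 96.8 CPM), Gm24270 (17.0, 7.72 and 47.4 CPM) and Gm24407 (5.42, 36.7 and 13.3 CPM), annotated as small RNA genes, also varied (adjusted p = 0.00212, 0.00789 and 0.00789), and reads of repeated small RNA copies are uncertain in their assignment. With a replicate left out, 28 genes were called without replicate 1 (27 of them among the 39), 47 without replicate 2 (24 of them) and 16 without replicate 3 (16 of them).

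**Figure D2:**
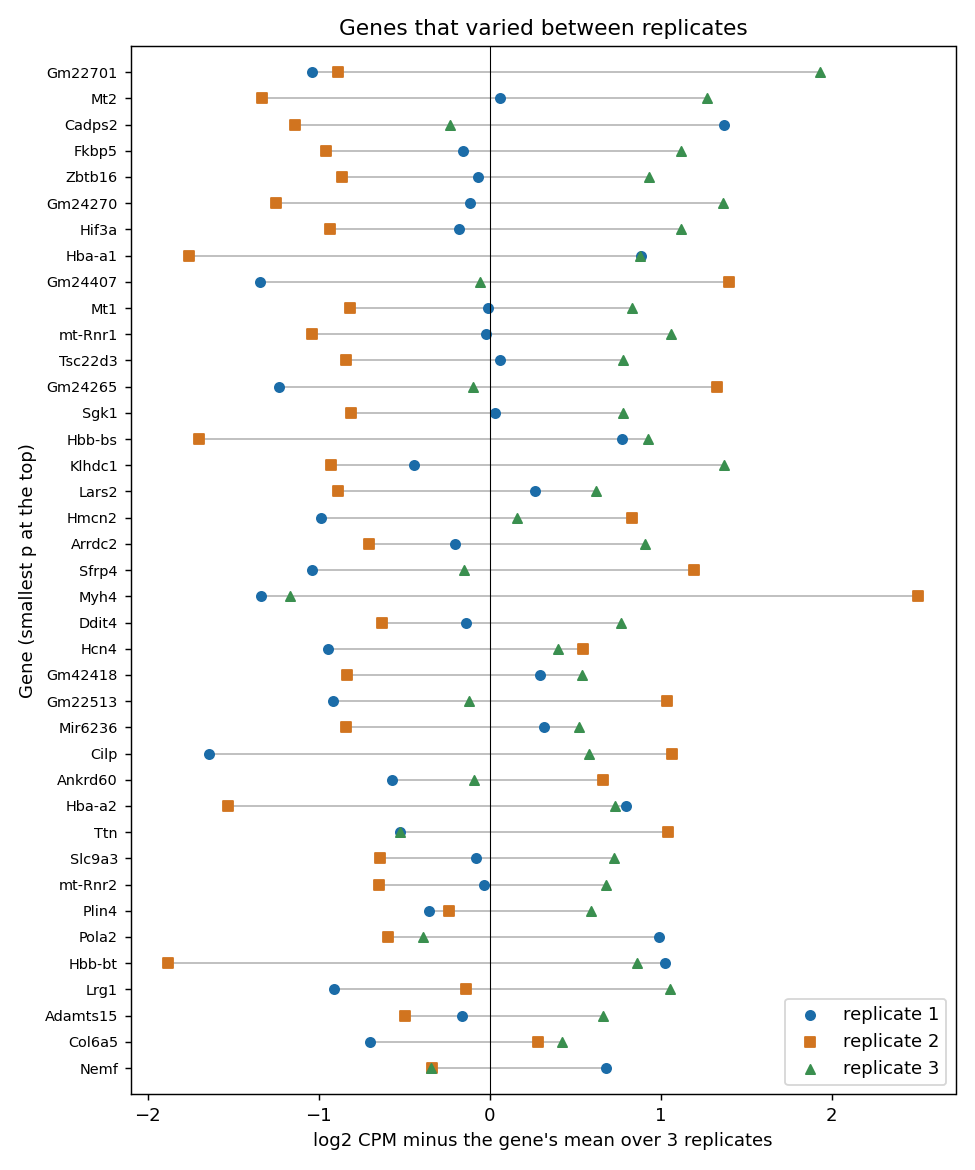
The 39 genes that varied between replicates, each with its log2 CPM in the 3 libraries minus its own mean, smallest p at the top. Mt2, Fkbp5, Zbtb16, Hif3a and Mt1 lie in the order replicate 2, 1, 3 from left to right, the 4 haemoglobin genes are low in replicate 2 and Myh4 is high there.

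Blood and muscle transcripts set replicate 2 apart. All 4 haemoglobin genes of the 7 in the erythroid list varied, and were lower in replicate 2 than in the others, while the detected member Alas2, named after its values were seen, had 7.04, 7.95 and 6.65 CPM. Hba-a1 had 29.0, 4.59 and 28.9 CPM (adjusted p = 0.00789), Hbb-bs 24.7, 4.40 and 27.5 CPM (0.00822), Hba-a2 19.1, 3.75 and 18.2 CPM (0.0173) and Hbb-bt 8.95, 1.14 and 7.99 CPM (0.0491). The copies of each globin are near-identical, so their separate values are uncertain. The list summed to 89.3, 21.9 and 89.8 CPM. Of the 15 skeletal muscle genes 4 were detected, led by Ttn, Actn3 (7.27 ± 1.79 CPM) and Eno3 (6.39 ± 1.07 CPM). Myh4, a fast muscle myosin, had 0.746, 11.6 and 0.845 CPM (adjusted p = 0.0105), and titin, Ttn, had 12.1, 35.9 and 12.1 CPM (0.0226). The muscle list summed to 32.3, 81.4 and 29.7 CPM, while Tnnc2 had 0 counts throughout. When adjusted over the list alone, 4 erythroid and 4 muscle genes passed. Here and below, that adjustment does not correct for the number of lists. Both lists stood at the 100th percentile of random lists for their shift, and at 37.8 and 17.3 without replicate 2.

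The perineurial and adipocyte lists stood lowest in replicate 1. The perineurial list had a mean shift of -0.31, 0.14 and 0.17 log2 units in replicates 1, 2 and 3 (100th percentile). Its most abundant member, Itgb4, was lowest in replicate 3 (1078, 1278 and 1033 CPM), and the other members were lowest in replicate 1. None of the list's 8 members passed the test over all genes, while 6 passed when adjusted over the list alone. Among the 6 (chosen after their values were seen) were Klf5 (32.6, 55.4 and 57.5 CPM) and Slc2a1 (159, 204 and 226 CPM). The adipocyte list shifted by -0.26, 0.06 and 0.21 (100th percentile). Its member Plin4, a lipid droplet gene, passed the test over all genes with 104, 112 and 199 CPM (adjusted p = 0.0471), and 6 members passed when adjusted over the list alone. The fibroblast and collagen list shifted by -0.13, 0.07 and 0.06 (99.9th percentile; 0 members called over all genes and 3 adjusted over the list alone, Pi16, Sox9 and Pcolce2, named after their values were seen). That mean gives equal weight to members of low abundance: by the median of its members' shifts (-0.04, -0.06 and 0.07) and by the sum (18097, 16707 and 19917 CPM) the list was lowest in replicate 2. Without replicate 1 the perineurial and fibroblast lists fell to the percentiles 37.3 and 20.4, and the adipocyte list stayed at 98.2.

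Of the 26 lists with enough tested members, 14 reached the 95th percentile, where 1.3 would do so if genes were independent. Beside those above they were mast cell (-0.27, -0.25 and 0.52), macrophage (0.07, -0.17 and 0.09), mitochondrially encoded (-0.12, -0.06 and 0.17), cholesterol synthesis (-0.10, -0.02 and 0.12), circadian clock (-0.12, 0.01 and 0.11), interferon response (-0.15, 0.11 and 0.04), pericyte and smooth muscle (-0.12, -0.02 and 0.14), immediate early (-0.10, -0.02 and 0.12) and myelin (0.07, -0.08 and 0.01). None of these 9 lists had a member called over all genes. Adjusted over the list alone, there were 3 calls in the clock list (Per1, and Per2 and Dbp, named after their values were seen), 3 in the immediate early list (Nr4a1 and Zfp36, and Dusp1, named after its values were seen), 2 in the mast cell list (Kit and Tpsb2), 1 in the macrophage list (Cd163), and 1 in the injury list, Atf3, at 15.1, 16.2 and 8.06 CPM. Shifts of the endothelial (percentile 47.4), neuron and axon (30.6), NAD metabolism (22.3) and dendritic cell (23.6) lists were within the range of random lists. Those of non-myelinating Schwann (80.9), injury (73.7), monocyte (93.3), MHC class II (94.6), B and plasma cell (90.3), cytokine (74.97), complement (71.9) and cell cycle (80.3) genes were below the 95th percentile. With list medians in place of means, MHC class II and monocyte genes reached 99.77 and 98.26. MHC class II genes also reached 95.11 with no scaling factors. Of the 14, only the cholesterol synthesis and adipocyte lists stayed at or above the 95th percentile with each library left out in turn. Without replicates 1, 2 and 3 they stood at 99.17, 99.99 and 97.1, and at 98.19, 100 and 99.99. The erythroid, muscle, perineurial and fibroblast lists fell as given above. Without replicate 3 the mast cell list fell to the percentile 8.61, and the mitochondrially encoded, immediate early and pericyte lists to 76.0, 76.0 and 73.5. The macrophage and myelin lists fell to 21.2 and 88.4 without replicate 2. Without replicate 1 the interferon, pericyte, clock and immediate early lists fell to 57.8, 91.8, 91.6 and 91.1. In all, 8, 12 and 11 lists reached the 95th percentile without replicates 1, 2 and 3 in turn. Some of these were not among the 14: monocyte (96.92) and MHC class II (95.8) without replicate 2, and MHC class II (96.85) without replicate 3.

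**Figure D3:**
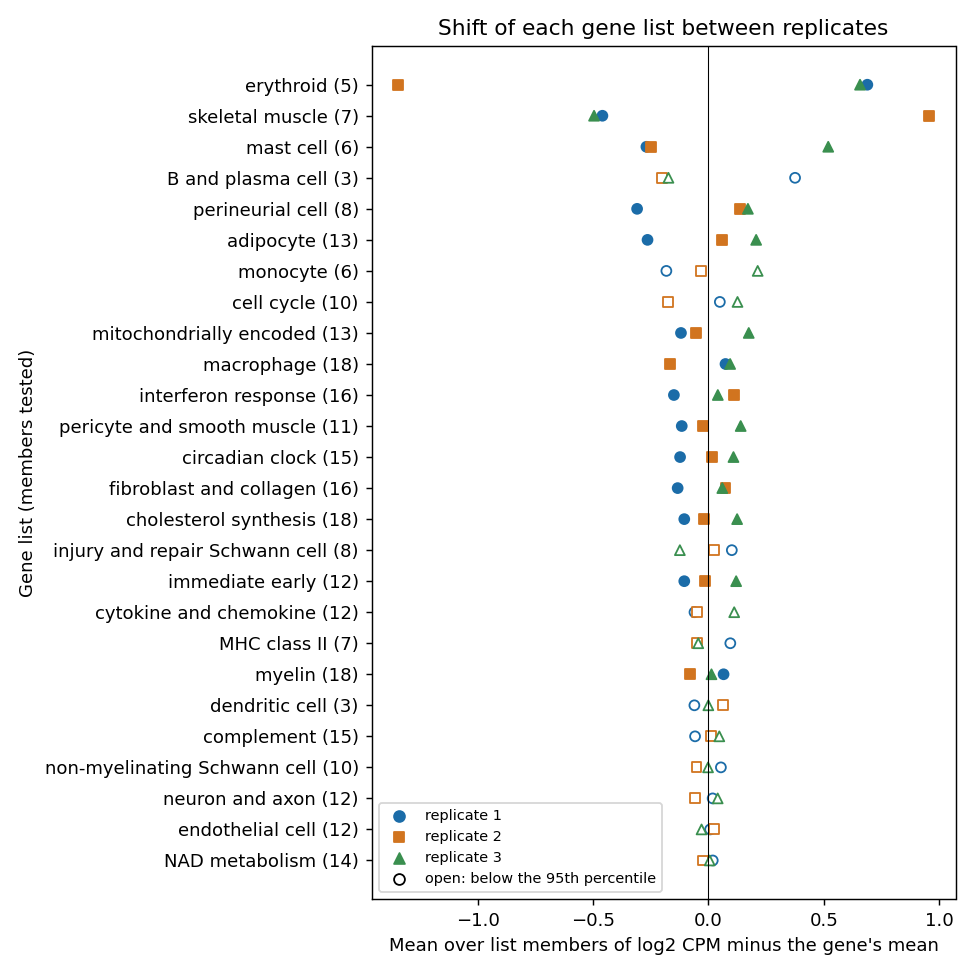
Mean over tested members of log2 CPM minus the gene's own mean, per replicate, for the 26 lists with at least 3 tested members (number in parentheses); filled symbols mark the 14 lists at or above the 95th percentile of random lists. Erythroid and skeletal muscle genes spread most, with replicate 2 at -1.35 and 0.96.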

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

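The counts divided by 2, the list sums per kb and the legacy=FALSE option of edgeR below were chosen after seeing the data. Levels of Sarm1, Nmnat2 and the lists stayed within 1 SD with DESeq2 size factors and with mitochondrial genes left out (which leaves 28 lists). They also did so with each replicate left out. At equal scaling, however, the mean of 2 of 3 values always lies within 1 SD of the mean of all 3. Leaving out a replicate therefore says nothing on how steady the levels are. The number of detected genes and the coefficient of variation stayed within 1.5 times under these settings, as did the coefficient with no scaling factors. So did the number of detected genes at limits of 0.5 and 5 CPM, 16421 and 11090. The coefficient was 10.3% to 11.3% with a replicate left out, 11.9% with no filter and 8.62% with counts divided by 2. Per kb of exon, 28 of 29 list sums moved, because the unit differs. The number of genes that varied, 39, became 141 with no filter, 196 with the goodness-of-fit test and 189 as DESeq2 dispersion outliers, each including the 39, and 16 to 47 with a replicate left out (28, 47 and 16 without replicates 1, 2 and 3, sharing 27, 24 and 16 with the 39). It was 0 with robust=TRUE (613 genes at an unadjusted p under 0.05), which lowers the prior degrees of freedom of variable genes, to 0.183 at the lowest, so that no gene stood out; counts divided by 2 gave 32 and legacy=FALSE 34. Lists at the 95th percentile numbered 8 to 12 with a replicate left out, not all of them among the 14 of the main setting, and 11 stood at the 99th. At the 95th there were 15 with no scaling factors, 16 with list medians, and 14 with DESeq2 size factors or a prior count of 0.5. Leaving out replicates moved the log2 ratios little: 4.24 to 4.40 for myelin over non-myelinating Schwann genes, 9.34 to 9.50 over injury genes, and for macrophage genes 6.16 to 6.68 over T and NK, 5.60 to 5.97 over neutrophil, 4.70 to 5.09 over B and plasma cell and 3.34 to 3.63 over monocyte genes. Without length scaling they were 3.06 and 9.83, and 5.54, 6.24, 5.35 and 2.52. With means over members they were 6.09 and 7.79, and 6.43, 5.09, 3.62 and -0.01337, so the last reversed. With detected members only, the ratio over injury genes was 5.74, over neutrophil 2.83, over B and plasma cell 0.62 and over monocyte genes 1.28; no T and NK gene was left. No paired analysis was possible because there is 1 group. The depth limits what can be said of genes under about 0.1 CPM, or under a higher level if both mates of a read pair were counted.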

Other observations

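The genes in this paragraph were named after their values were seen, and no test was made of them as a set. Sfrp4, a secreted Wnt antagonist, had 8.14, 38.6 and 15.2 CPM in replicates 1, 2 and 3 (edgeR adjusted p = 0.0101), the cartilage and tendon protein gene Cilp had 2.76, 18.3 and 13.1 CPM (0.0166), Hmcn2 had 19.4, 68.7 and 43.0 CPM (0.00948) and Col6a5 had 30.9, 61.2 and 67.4 CPM (0.0491). These 4 were lowest in replicate 1, while the matrix protease gene Adamts15, with 37.6, 29.8 and 66.8 CPM (0.0491), was lowest in replicate 2. Klhdc1 (chromosome 12, 69241176 to 69284632) and Nemf (chromosome 12, 69310522 to 69357165) lie near each other and varied in different libraries, with 9.70, 6.91 and 34.2 CPM against 66.6, 33.0 and 32.8 CPM. Gm42418 (848, 388 and 1007 CPM), Lars2 (123, 55.4 and 158 CPM), Mir6236 (78.4, 35.0 and 90.1 CPM) and mt-Rnr1 (29.5, 14.6 and 62.6 CPM) were all lowest in replicate 2 and highest in replicate 3. Xaf1, the highest of the interferon list, lies 6.17 Mb from Sarm1 on chromosome 11.

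The tests of Y-linked counts were chosen after the values were seen. Those of glucocorticoid and mitochondrial genes were set before theirs, although the 8 called glucocorticoid genes were picked after. For mitochondrial genes, only Spearman's rho and its permutation p were set before, and Pearson's r was not part of that plan.

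The 8 glucocorticoid-induced genes among those that varied (Fkbp5, Zbtb16, Tsc22d3, Sgk1, Mt1, Mt2, Ddit4 and Hif3a) were all highest in replicate 3 and lowest in replicate 2. A list of 15 other glucocorticoid-induced genes, none of them called, shifted by -0.03, -0.22 and 0.25 log2 units in replicates 1, 2 and 3, and 13 of the 15 had the order replicate 3, 1, 2, as did 17.2% of all tested genes and 19 of the 39 called; genes co-vary, so this is a description without a test. Its SD was at the 100th percentile of random lists, and at 99.4 or above with each replicate left out. Since 14 of 26 fixed lists reached the 95th, the size matters more. Only 1 of the 17 fixed lists with 10 or more tested members had a larger SD. Among smaller lists, the erythroid, skeletal muscle, mast cell, B and plasma cell and perineurial lists had larger SDs. These were 1.17, 0.83, 0.45, 0.33 and 0.27, against 0.235 for the list of 15 glucocorticoid-induced genes. A trend of GC content between libraries is argued against, since the list stayed at the 100th percentile among lists matched on GC content. The hypothesis that the nerves differed in glucocorticoid exposure is consistent with the percentile of 100, but Gm42418, Lars2, Mir6236, mt-Rnr1 and mt-Rnr2 (40.3, 26.3 and 66.0 CPM) had that order too, so RNA composition or quality, which was not tested, stays open, as do handling, time of day and pooling.

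Y-linked counts were far higher in replicate 1 than in replicates 2 and 3, although Xist was abundant in all 3 libraries. Ddx3y, Kdm5d, Uty and Eif2s3y summed to 497, 7 and 2 counts. Assignment of reads from their X-linked partners Ddx3x, Kdm5c, Kdm6a and Eif2s3x is argued against: per partner count, the Y-linked counts in replicate 1 were 107 times those of replicates 2 and 3 (exact 95% interval 55.7 to 234, counting error only), while the partners summed to 15452, 15426 and 14384 counts. Some male RNA or reads in that library may be the source. Its Xist level differed from the mean of the others by -0.19 log2 units, within a spread of 0.19, so the male share, and whether it came from pooling, carry-over or sample indexes, cannot be told apart here.

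Mitochondrially encoded genes differed widely for transcripts of shared precursors. The 5 genes with over 90% of their 50-base stretches present in nuclear transcripts (mt-Co2, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l) had 14.5 to 87.2 CPM per kb, and the others, except mt-Atp8, had 241 to 1910 CPM per kb. Reads shared with nuclear copies and left out of the counts may contribute, but over all 13 genes Spearman's rho was -0.44 (permutation p = 0.13) and Pearson's r was -0.58 (permutation p = 0.043; -0.846 to -0.449 when any 2 of the 4 genes tied as farthest from the median share, mt-Atp8 among them, were left out), and genes are not independent replicates. The relation missed the limit set in advance because mt-Atp8, with none of its 50-base stretches in nuclear transcripts, had 23.9 CPM per kb. Nuclear copies outside annotated transcripts were not searched, so mt-Atp8 may share sequence that this share leaves out. Without mt-Atp8 rho was -0.69, a choice made after seeing the data. No biological explanation was tested, and summed mitochondrial levels are uncertain by this spread.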
